A study of Mus musculus with 25 samples.

How the data were processed

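Reduced representation bisulfite sequencing (RRBS) reads methylation at CpG-rich restriction fragments: DNA is cut with an enzyme, treated with bisulfite and sequenced, so that an unmethylated cytosine reads as thymine. The 25 libraries came from haematopoietic stem cells of C57Bl/6 mice, from fetal liver or bone marrow, and the protocol was adjusted for small cell numbers, per the labels' protocols. Each deposited file lists CpGs with their position, strand, the methylated over the total reads and a score. The deposited score is a whole number made by the authors, and on the files it equalled the methylated share of the reads scaled up and rounded down. The authors' coordinates are on mm9, per the submitters' processing notes; the aligner, the methylation caller, read filters and the handling of duplicate reads are not given in the sources used here. Without molecular identifiers, reads are not independent molecules, so all counting errors are lower limits.

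The methylated and total reads were used as deposited, and the score was not tested. A library held between 22835325 and 105187091 reads over 1246435 to 1619487 CpGs, with a median of 10 to 54 reads per CpG. The deepest CpG of a library had between 63841 and 1411582 reads. Of the 2100083 CpGs seen in any library, 588138 had at least 5 reads in every library. No pair of libraries had identical counts; the highest correlation of CpG levels was 0.990, between both young libraries, and the lowest was 0.927.

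For each comparison, CpGs with at least 5 reads in every library of the fit were summed in tiles of 1000 bp, and tiles with at least 3 such CpGs on the 19 autosomes were tested. The labels give no sex, so chromosome X was tested only as an alternative. Methylated and total reads were fitted with a quasi-binomial (logistic) model with a mean per group. Libraries were weighted by Williams' method for reads that vary together within a library. The dispersion was moderated across tiles by empirical Bayes with a trend on depth, as limma does for variances, and held at 1 or more. P-values came from an F test and were adjusted by Benjamini-Hochberg over all tiles tested. A tile counted as changed at an adjusted p under 0.05 with a difference of at least 10 percentage points. Groups with few libraries shared a fit: fetal, young and old (6 libraries), young and the 5-fluorouracil (5-FU) groups (10 libraries), and young, old and the transplanted groups (15 libraries). Donor age after transplantation was fitted on the 11 transplanted libraries, with log10 of the number of cells as a covariate. The residual degrees of freedom were 3, 6, 7 and 8, and the prior degrees of freedom from the moderation were 1000000, 10.32, 29.43 and 34.06. In the fit of fetal, young and old the trend on depth thus replaced the dispersion of each tile. A tile's own spread between replicates did not enter its p-value there. Nothing in the labels says that replicates came from separate animals. The p-values therefore measure the spread between these libraries, pooled over tiles in that fit, which may be technical.

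The comparisons, tests and the first group of alternatives given below were fixed before the data were examined. The fits were tested on simulated reads with the depths of the real libraries and 200 changed tiles. The Williams' weights were added at that stage, before any fit of real data, because too many unchanged tiles passed without them. For old against young, with a simulated correlation of 0.01 within a library, 68.0% of differences of 20 points and 98.0% of 30 points were recovered, with 5 unchanged tiles called of 100896. For 10 young cells against young, simulated at 0.03, 28.0% and 48.0% were recovered, with 2 unchanged tiles called of 90382. The correlations later estimated in the real fits were lower, 0.0057 and 0.0083. In the second of these fits the dispersion also varied between tiles, which the simulated reads did not hold. The shares recovered and the unchanged tiles called therefore describe the simulated settings, not the real comparisons.

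Single values per library were compared with two-sided exact permutation tests. The age-gain score is the mean methylation of a library over tiles that gained with age, and the age-loss score that over tiles that lost; the tiles were chosen from old against young only, and the scores were compared between libraries that did not choose them. Of the tests of single values, 6 were planned and 20 were added after the values were seen, each family with its own Benjamini-Hochberg adjustment. Tiles named in the text follow a planned rule: the 5 largest gains and 5 largest losses of a main comparison (young against fetal, old against young, 10 young cells against young, 4 against 0 doses of 5-FU) and 3 of each for the others, among changed tiles where every library of one group lay above every library of the other.

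Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, limma 3.58.1 in R 4.3.3, and matplotlib 3.10.9. The alternatives planned were 10 or 3 reads per CpG, tiles of 300 bp, chromosome X included, a fit of all 25 libraries, a difference of 20 points, the replicate number as a block, each library left out in turn, limma on mean CpG fractions, and the 0-dose libraries as control for transplantation. Alternatives chosen after seeing the data were removal of each library's offset at CpG-rich tiles of intermediate level (between 25% and 75% in every library, at least 10 CpGs), CpGs over 500 reads left out, centring on the median difference, fits of only the groups compared, and scores less those of matched tiles. An annotation of mm9 was not used here, so tiles are given by position without genes, and the planned test of gene lists, with its alternative on promoter tiles, was not run. For shares by level, tiles were classed by a group in the fit but outside the comparison, since a level that includes the groups compared depends on the change itself; this classing was chosen after seeing the data. Coordinates are 1-based mm9 positions.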

Results

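DNA methylation was measured by RRBS in haematopoietic stem cells (HSCs), the blood-forming cells that renew themselves and give rise to all blood lineages. The 25 libraries covered fetal liver at e14.5 (n = 2), bone marrow of mice aged 3.5 months (young, n = 2) and 25 months (old, n = 2), mice kept for 6 more months after 3.5 months with 0 (n = 3), 2 (n = 3) or 4 (n = 2) doses of 5-FU, and HSCs recovered after transplantation. 5-FU kills dividing cells and drives surviving HSCs into cycle. The transplanted groups came from 10 (n = 3), 50 (n = 1) or 500 (n = 1) young cells and from 10 (n = 2), 50 (n = 1) or 500 (n = 3) old cells. Groups of 1 library have no replicate error. The design asked how methylation differs during ontogeny and ageing, and after a history of forced proliferation. Values are percent of reads methylated per 1-kb tile, on mm9.

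Between fetal liver and young bone marrow, 2768 tiles gained and 5293 lost methylation, of 100896 tested. The median gain of changed tiles was 18.0 points and the median loss was -19.1 points, while the median difference of all tiles was 0.197 points. Classed by their level in old HSCs, which are outside this comparison, 8.64% of tiles between 20% and 80% gained and 16.6% lost. Among tiles at 80% or more 2.56% gained and 3.63% lost, and among tiles under 20% 0.243% gained and 3.36% lost.

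The largest gain lay at chromosome 16, 92696001 to 92697000, with 87.8% ± 1.76 (SD, n = 2) in young against 1.29% ± 0.356 (n = 2) in fetal HSCs, over 290 to 837 reads per library. The neighbouring tile from 92695001 to 92696000 rose from 2.68% ± 1.01 to 73.4% ± 6.19. In the later groups the first tile read 71.0% to 90.6%; the neighbouring tile read 42.3% ± 15.5 with 4 doses of 5-FU. On chromosome 1, the tile 173123001 to 173124000, rose from 11.2% ± 0.202 to 79.5% ± 2.48, and the level in old HSCs was 85.5% ± 0.427. At chromosome 8, 11279001 to 11280000, the level was 15.6% ± 2.29 in fetal, 80.2% ± 2.00 in young and 89.7% ± 0.457 in old HSCs, but 37.4% to 53.4% in the 5-FU groups and 27.3% to 50.5% in the transplanted groups. The tile at chromosome 15, 31227001 to 31228000, rose from 9.94% ± 5.05 to 81.9% ± 18.6, with unequal depth of 20 to 32 reads in young and 157 to 370 in fetal libraries. Of the 5 largest losses, 4 lay on chromosome 8. The tile from 122906001 to 122907000 fell from 89.5% ± 1.86 to 2.51% ± 0.462 over 119 to 367 reads, that from 123168001 to 123169000 from 90.6% ± 6.58 to 5.28% ± 1.07, and that from 122794001 to 122795000 from 89.4% ± 5.53 to 8.59% ± 0.695. At chromosome 15, 82030001 to 82031000, the level fell from 90.6% ± 9.02 to 1.38% ± 0.244. Changed tiles also lay close together: 8 runs, with neighbours starting at most 2 kb apart, held 3 or more gained tiles, against at most 2 runs in 100 random draws of tiles. For lost tiles there were 6 runs, against at most 5. The draws were from all tested tiles and not matched on level or CpG number. The longest run covered 4 tiles at chromosome 11, 96203001 to 96208000, with a median gain of 33.1 points.

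The count of 8061 changed tiles was 1276 in a fit of all 25 libraries, 2843 with limma and 3600 at a difference of 20 points, in each case with more losses than gains. It was 3624 with the replicate number as a block. Leaving out fetal replicate 1 also lowered the count, again with more losses than gains.

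Old HSCs differed from young HSCs mainly by gains. Of 100896 tiles, 5832 gained and 404 lost, so that 93.5% of the changed tiles gained. The median gain was 18.7 points. Classed by their level in fetal HSCs, which are outside this comparison, 18.3% of tiles between 20% and 80% gained, against 3.72% at 80% or more and 2.64% under 20%. Within the tiles between 20% and 80%, 38.4% of those with 30 or more CpGs gained, 23.6% of those with 10 to 29 and 16.5% of those with fewer than 10. The median difference of the tiles in the first of these classes was 9.22 points. Old libraries also read higher than young ones at CpG-rich tiles of intermediate level in every library, as given below. The shares by class were not computed with this offset removed, so they cannot be told apart from it. Gained tiles formed 12 runs of 3 or more, against at most 5 in 100 random draws, which were not matched on level or CpG number.

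The largest gain was at chromosome 15, 49801001 to 49802000, with 97.0% ± 2.64 (SD, n = 2) in old and 10.1% ± 1.65 (n = 2) in young HSCs. The depth of this tile was unequal, 7974 to 8314 reads in young and 86 to 184 in old libraries, and fetal HSCs had 88.4% ± 6.05 there. A tile at chromosome 8, 125806001 to 125807000, had lost methylation from fetal to young HSCs and stood at 90.02% ± 13.0 in old against 9.09% ± 12.9 in young, over as few as 22 reads. At chromosome 7, 12791001 to 12792000, the level was 94.3% ± 0.583 in old and 14.6% ± 9.89 in young. The tiles at chromosome 5, 124567001 to 124568000, and chromosome 19, 24587001 to 24588000, rose to 94.1% ± 4.84 and 89.3% ± 12.3, with 21 and 15 reads in the thinnest library. The largest loss lay at chromosome 2, 33616001 to 33617000, from 68.8% ± 0.281 to 10.3% ± 4.33 over 197 to 416 reads. Losses at chromosome 12, 104452001 to 104453000, from 64.3% ± 2.25 to 12.1% ± 4.28, and chromosome 17, 74202001 to 74203000, from 82.5% ± 3.54 to 30.9% ± 4.50, and chromosome 1, 77367001 to 77368000, from 83.2% ± 0.946 to 31.2% ± 15.8, were also among the named tiles. The loss at chromosome 6, 112995001 to 112996000, rested on a young group at 46.0% ± 43.7, a spread that did not enter its p-value.

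At 57 CpG-rich tiles of intermediate level in every library, young libraries read 43.5% to 44.4% and old libraries 52.1% to 53.9%. With this offset of each library removed, a setting chosen after seeing the data, 1941 tiles gained and 1049 lost, so that 64.9% of the changed tiles gained. With the replicate number as a block, 2380 tiles changed. The count of changed tiles was 180 in a fit of all 25 libraries, of which 160 gained, and 521 with limma, of which 499 gained; it was 2267 without old replicate 1, 2877 without young replicate 1, 4003 without old replicate 2 and 2726 at a difference of 20 points.

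**Figure D1:**
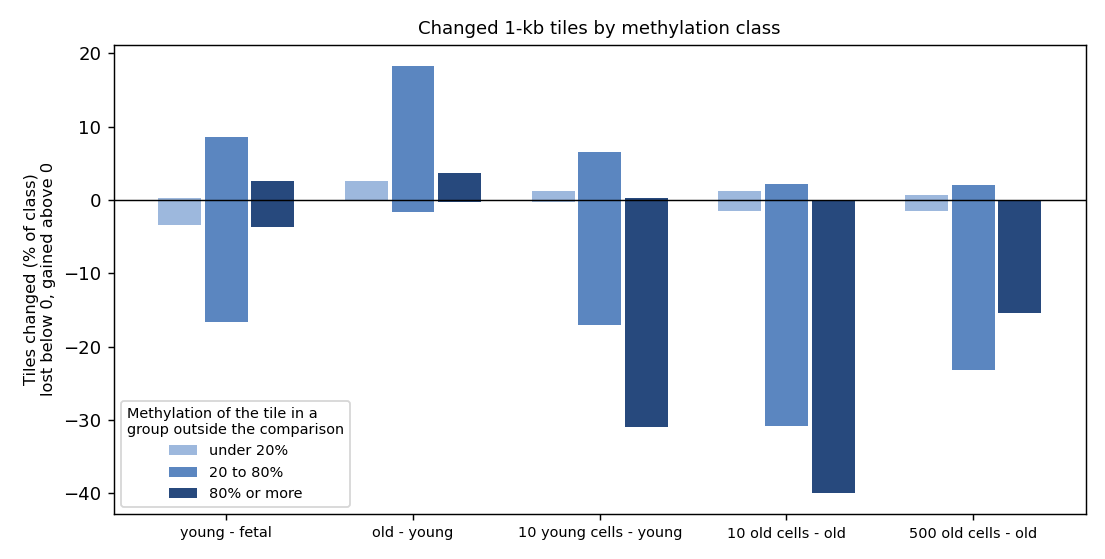
Share of tested 1-kb tiles that gained (above 0) or lost (below 0) methylation, in percent of the tiles of each class, for 5 comparisons, with no library offset removed. Tiles are grouped by their methylation in a group outside the comparison (old HSCs for young against fetal and for 10 young cells, fetal HSCs for old against young, young HSCs for old cells); old against young shows 18.3% of tiles between 20% and 80% gained, and 10 young cells against young shows 31.0% of tiles at 80% or more lost.

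HSCs of the 0-dose group, which had 6 more months without drug, differed from young HSCs at 237 of 57204 tiles, with 208 gains and 29 losses. The largest gain was at chromosome 17, 64051001 to 64052000, with 97.4% ± 4.44 (SD, n = 3) against 8.01% ± 2.89 (n = 2). Gains also included chromosome 4, 118170001 to 118171000 (96.5% ± 0.191 against 12.1% ± 17.1) and 134412001 to 134413000 (80.8% ± 11.2 against 9.0% ± 1.41). The largest loss was at chromosome 4, 127033001 to 127034000, with 9.54% ± 2.10 against 83.9% ± 4.3. Smaller losses were at chromosome 10, 8269001 to 8270000, and chromosome 1, 184187001 to 184188000, where the 0-dose group had 43.4% ± 21 and 47.4% ± 10.2. The count depended on both young libraries, being 29 without young replicate 1 and 81 without young replicate 2, and 127 and 119 without 0-dose replicates 1 and 3; it was 92 with the replicate number as a block, 388 with 300-bp tiles, 596 in a fit of all 25 libraries, 760 with limma and 2883 in a fit of only the groups compared. With the offset removed, 100 tiles gained and 52 lost, a share of 65.8% gained in place of 87.8%. The 0-dose libraries also stood apart technically. Their deepest CpG had 63841 to 74120 reads, against 101345 or more in every other library. Of their CpGs 56.9% to 57.2% were listed on the plus strand, against 57.7% or more elsewhere. A difference in preparation was not tested and cannot be told apart from the 6 months. The same group is the control of the 5-FU comparisons and of the planned score tests.

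After 5-FU the number of tiles that differed from the 0-dose group was small but moved widely with the setting. With 2 doses 12 tiles gained and 13 lost, and with 4 doses 2 gained and 4 lost, of 57204. In a fit of all 25 libraries, with 300-bp tiles, with the replicate number as a block and in a fit of only the groups compared, the counts were 216, 117, 119 and 38 with 2 doses and 386, 73, 0 and 615 with 4 doses. They were 50 and 60 with limma and 40 and 33 with at least 10 reads per CpG. The count of 0 is that of the quasi-binomial test with the block, which had 327 of 60272 tiles at an unadjusted p under 0.05. On chromosome 4, 4270001 to 4271000 was at 76.6% ± 8.27 (SD, n = 3) with 0 doses, 7.59% ± 1.54 (n = 3) with 2 and 10.7% ± 1.41 (n = 2) with 4. At chromosome 1, 136049001 to 136050000, the levels were 86.4% ± 5.55, 30.9% ± 1.74 and 34.8% ± 0.647. With 4 doses the tiles at chromosome 11, 103934001 to 103935000, and chromosome 1, 7732001 to 7733000, had 7.71% ± 0.022 and 13.0% ± 2.25, against 52.5% ± 3.74 and 56.3% ± 10.8 with 0 doses. In young HSCs, without 5-FU, these 4 tiles read 15.6% ± 1.61, 42.8% ± 6.97, 11.3% ± 0.696 and 13.9% ± 1.64 (n = 2), so that the 0-dose group stood apart from young HSCs as well. In these tiles depth differed together with level: at chromosome 11 the 4-dose libraries had 4413 to 6835 reads and the 0-dose libraries 132 to 241, and at chromosome 4 the 2-dose libraries had 3628 to 4892 and the 0-dose libraries 88 to 153. With CpGs over 500 reads left out, chosen after seeing the data, 3 tiles gained and 0 lost with 4 doses. The loss at chromosome 11, 103934001 to 103935000, reversed to a higher level with 4 doses in that setting, and also with limma.

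Both gains with 4 doses, at chromosome 3, 10440001 to 10441000, and chromosome 11, 53244001 to 53245000, reached 42.4% ± 12.9 and 35.6% ± 19.9, against 0.306% ± 0.530 and 0.204% ± 0.354, over the 3 and 5 CpGs shared by the 10 libraries. Over the 10 and 9 CpGs covered in both 4-dose libraries, that group read 13.0% ± 1.81 and 14.6% ± 4.36. With 2 doses, gains included chromosome 11, 67736001 to 67737000 (51.6% ± 7.66 against 13.3% ± 5.77), chromosome 15, 101931001 to 101932000 (43.6% ± 5.56 against 4.64% ± 6.27), and chromosome 9, 123439001 to 123440000 (37.3% ± 1.96 against 2.05% ± 1.81). The tile at chromosome 17 named above fell from 97.4% ± 4.44 to 40.2% ± 19.4 with 2 doses. Replicates of the 4-dose group differed by a median of 12.7 points per tile, against 3.88 points in the young group, and its count was 930 without replicate 1 and 17 without replicate 2 of that group. For 2 doses the count was 88 without 2-dose replicate 3 and 13, 14 and 15 without 0-dose replicates 3, 2 and 1. With the offset removed, 19 tiles gained and 11 lost with 2 doses, 63.3% gained in place of 48.0%. At an unadjusted p under 0.05, 5.70% of tiles passed with 2 doses and 9.94% with 4.

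Transplantation went with loss of methylation at most of the changed tiles. With 10 young cells, 18276 tiles lost and 1243 gained relative to young HSCs, of 90382 tested, and the median difference of all tiles was -4.47 points. With 10 old cells, 24278 tiles lost and 640 gained relative to old HSCs, with a median difference of -6.48 points. With 500 old cells, 11192 lost and 516 gained, with a median of -3.83 points. Loss was frequent at CpG-poor tiles: 30.5% of tiles with fewer than 10 CpGs lost with 10 young cells, against 0.344% of tiles with 30 or more, and the shares with 10 old cells were 38.9% and 1.10%. Of the 13386 tiles with 30 or more CpGs, 11348 were under 20% in old HSCs, where there is little room for a loss of 10 points. Among tiles at 80% or more in old HSCs, 37.4% of those with fewer than 10 CpGs lost with 10 young cells. With 30 or more CpGs 1.87% did. Among all tiles with 30 or more CpGs, 188 gained and 46 lost with 10 young cells, at a median difference of -0.596 points. With 10 old cells 33 gained and 147 lost. Of tiles with 30 or more CpGs between 20% and 80% in old HSCs, 35.2% gained and 3.17% lost with 10 young cells. Young libraries read lower than all other untransplanted libraries at CpG-rich tiles of intermediate level (43.5% and 44.4% against 46.6% to 53.9%), and with the offset removed the gained tiles with 10 young cells numbered 688 in place of 1243. By level in old HSCs, 17.0% of tiles between 20% and 80%, 31.0% at 80% or more and 0.304% under 20% lost with 10 young cells. By level in young HSCs, the shares were 30.9%, 39.9% and 1.49% with 10 old cells and 23.2%, 15.4% and 1.48% with 500 old cells.

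The largest loss with 10 young cells was at chromosome 8, 96959001 to 96960000, from 85.3% ± 1.82 (SD, n = 2) to 23.04% ± 6.48 (n = 3), followed by chromosome 11, 70327001 to 70328000, from 86.5% ± 7.81 to 31.1% ± 21.5, and chromosome 4, 86358001 to 86359000, from 67.6% ± 1.55 to 8.16% ± 1.23. Losses at chromosome 5, 114822001 to 114823000, and chromosome 7, 17369001 to 17370000, ended at 18.9% ± 8.27 and 33.3% ± 5.31. With old cells the largest loss was at chromosome 7, 56123001 to 56124000, from 93.9% ± 1.43 to 8.90% ± 0.363 after 10 cells and 14.6% ± 18.6 after 500 cells. The tile at chromosome 8, 108215001 to 108216000, fell from 93.6% ± 1.17 to 32.2% ± 32.3 and 22.5% ± 32.7, over as few as 18 reads. Further losses were at chromosome 17, 26191001 to 26192000, which fell to 21.9% ± 12.3 with 10 old cells, and chromosome 18, 38625001 to 38626000, which fell to 15.2% ± 5.58 with 500.

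The tile at chromosome 8, 125198001 to 125199000, was among the named gains of every comparison of transplanted with untransplanted HSCs. Its level was 21.3% ± 2.38 in young and 16.7% ± 4.28 in old HSCs, and 77.2% ± 8.71, 75.8% ± 3.92 and 70.1% ± 7.63 after 10 young, 10 old and 500 old cells, over 167 to 473 reads. Fetal HSCs and the 0-dose group also read above young and old there, as given under other observations. Tiles within a few kb of each other on chromosome 11 gained as well: 115969001 to 115970000 rose from 16.6% ± 2.94 to 71.2% ± 7.11 with 10 young cells, and 115967001 to 115968000 from 29.2% ± 2.76 to 88.8% ± 1.91 with 500 old cells. On chromosome 14, 64632001 to 64633000 rose from 13.1% ± 4.82 to 92.5% ± 7.03 with 10 and 67.7% ± 23.4 with 500 old cells. The tile at chromosome 2, 33616001 to 33617000, which had lost methylation with age, stood at 64.6% ± 7.55 after 10 old cells. With 10 young cells, gains at chromosome 15, 49801001 to 49802000 (75.1% ± 10.5 against 9.73% ± 1.60, with the unequal depth given above), chromosome 4, 43043001 to 43044000 (72.7% ± 22.8 against 12.1% ± 10.1), and chromosome 8, 87245001 to 87246000 (83.1% ± 11 against 33.5% ± 18.4), complete the named tiles. Against the 0-dose group as control the first and second of these reversed, by -13.5 and -4.10 points.

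Changes after 10 young cells, set against young HSCs, and after 10 old cells, set against old HSCs, shared no library. Both lists shared 12016 lost tiles, where lists drawn independently from all tiles would share 4909, and 310 gained tiles, where 8.80 would be expected. These expectations do not allow for level or CpG number, and losses in both lists lay mostly at CpG-poor tiles. Both lists also came from the same fit, with a shared dispersion per tile. The excess is therefore not a measure of independent agreement. Across all 90382 tiles the Spearman correlation of the differences was 0.695; tiles are not independent replicates.

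The transplanted counts moved with the setting while losses stayed in the majority. Centred on the median difference, chosen after seeing the data, 10214, 11794 and 7308 tiles lost with 10 young, 10 old and 500 old cells. In the same order 1578, 772 and 612 gained. At a difference of 20 points the counts were 4224, 7091 and 3182. A fit of all 25 libraries gave 2953, 4141 and 914 changed tiles for 10 young, 10 old and 500 old cells, and a fit of only the groups compared gave 20308, 40198 and 20141. With the replicate number as a block the counts were 2135, 21855 and 4742, and with limma 10380, 18459 and 5539. Without young replicate 2 the count for 10 young cells was 4765; without old replicate 1 the counts for 10 and 500 old cells were 10834 and 2618, without old replicate 2 they were 13856 and 4340, without replicate 1 of the 10 old cells 12613, and without replicate 1 of the 500 old cells 6415.

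**Figure D2:**
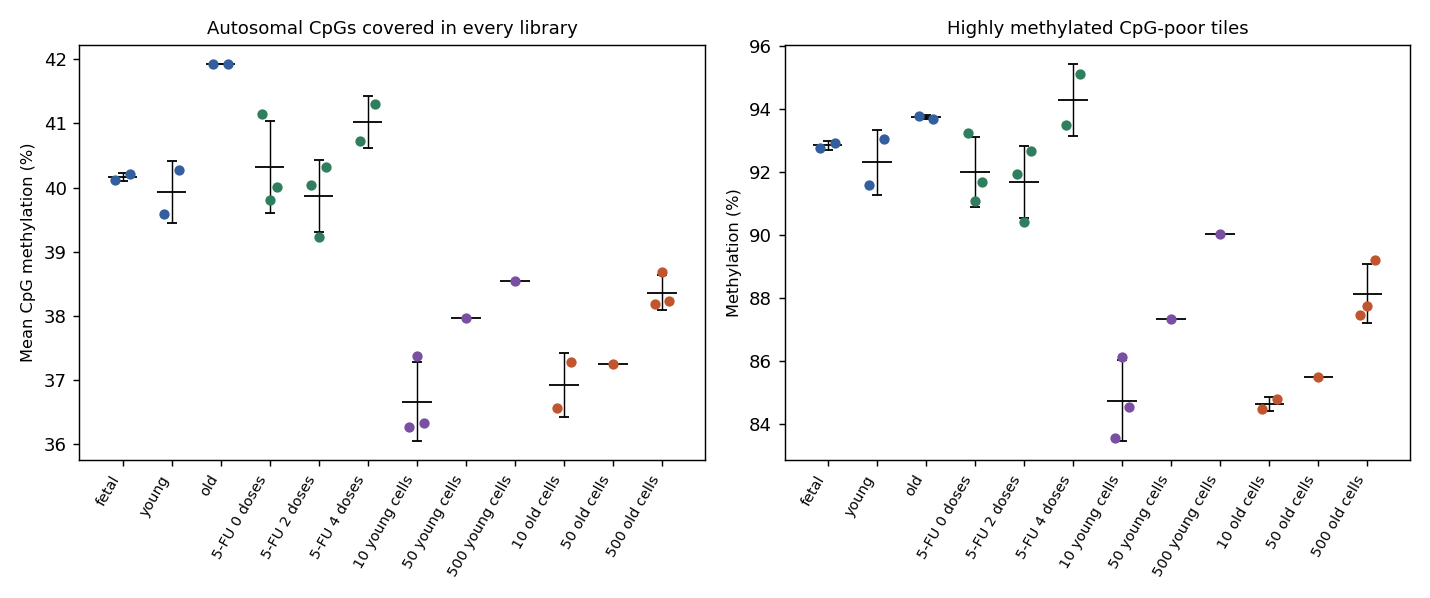
Mean methylation per library in percent, over 568553 autosomal CpGs with at least 5 reads in every library (left) and over 7408 CpG-poor tiles chosen for 80% or more in each of the 14 untransplanted libraries, which holds those libraries high (right). Points are libraries, long lines are group means and error bars are SD; the 11 transplanted libraries lie between 36.3% and 38.7% on the left, below the 14 others at 39.2% to 41.9%.

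Mean methylation over 568553 autosomal CpGs was 40.2% ± 0.0576 (SD, n = 2) in fetal, 39.9% ± 0.480 (n = 2) in young and 41.9% ± 0.0074 (n = 2) in old HSCs. The difference of 1.99 points between old and young had an exact permutation p of 0.333, the smallest that 2 against 2 libraries can give, and that of -0.229 points between young and fetal had an exact permutation p of 1.0. With reads pooled over CpGs the old minus young difference was 10.0 points, and with the offset removed it was -0.692 points. All 11 transplanted libraries, at 36.3% to 38.7%, lay below the 14 others, at 39.2% to 41.9%. Young-donor libraries averaged 37.3% ± 0.996 (n = 5), against 40.3% ± 0.719 (n = 3) with 0 doses, with an exact permutation p of 0.0179, the smallest possible, and 0.0716 after adjustment over the 20 added tests. Libraries from 500 cells had 38.4% ± 0.243 (n = 4) and those from 10 cells 36.8% ± 0.523 (n = 5), with an exact permutation p of 0.0079, the smallest possible, and 0.0527 adjusted. At highly methylated CpG-poor tiles the same groups had 88.6% ± 1.21 and 84.7% ± 0.922, with the same exact p and adjusted p; the ranges did not overlap in either measure. The tile-wise comparison of 10 with 500 old cells called 0 of 90382 tiles by the quasi-binomial test and 0 by limma, with 6693 and 10253 tiles at an unadjusted p under 0.05. Libraries from 2 and 4 doses of 5-FU averaged 40.3% ± 0.773 (n = 5), 0.0028 points from the 0-dose group, with an exact permutation p of 1.0.

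Few tiles were called for donor age after transplantation. On simulated reads this fit recovered 8.0% of differences of 10 points and 56.0% of 20 points, so a low count does not show that differences are absent. It is also not comparable with the 6236 tiles of old against young, where the dispersion was fully pooled over tiles. With the number of cells in the model, 9 tiles were higher and 1 lower in the 6 libraries from old donors than in the 5 from young donors, of 93599, and 5.44% of tiles passed an unadjusted p under 0.05. The tile at chromosome 5, 140740001 to 140741000, had 79.5% ± 6.37 (SD, n = 6) against 51.9% ± 19.6 (n = 5), and that at chromosome 17, 5152001 to 5153000, had 62.5% ± 8.05 against 40.8% ± 10.2. The count was 0 with limma (6940 tiles at an unadjusted p under 0.05), 0 without the library from 500 young cells and 78 without the one from 50 young cells. It was also 44 and 19 without replicates 1 and 2 of the 10 young cells, 20 and 3 without replicates 1 and 2 of the 10 old cells, 24 without replicate 3 of the 500 old cells and 5 without the library from 50 old cells. With the offset removed, 17 tiles were higher and 5 lower, so that 77.3% were higher. The count was 51 with 300-bp tiles, 33 with the replicate number as a block and 0 in a fit of all 25 libraries.

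Regions that changed with age were then followed in libraries that had not served to choose them. Over 2152 age-gain tiles covered in every library, young libraries scored 42.4% and 45.4% and old libraries 60.6% and 63.0%. The 0-dose libraries scored 54.9% ± 0.922 (SD, n = 3) and the fetal libraries 50.3% ± 0.0928 (n = 2). Young-donor libraries scored 45.2% ± 2.84 (n = 5), and the difference of -9.69 points from the 0-dose group had an exact permutation p of 0.0179, the smallest possible, with 0.0537 after adjustment over the 6 planned tests. All 5 libraries lay below the 0-dose range. Over 174 age-loss tiles the young-donor libraries scored 49.9% ± 1.15 (n = 5) and the 0-dose libraries 57.6% ± 0.145 (n = 3), a difference of -7.64 points with the same exact p and adjusted p. Relative to unchanged tiles matched on fetal level and CpG number, a comparison chosen after seeing the data, the difference was -4.92 points at age-gain tiles (exact permutation p = 0.0179, 0.0716 adjusted) and -0.222 points at age-loss tiles (exact permutation p = 0.875). With at least 10 reads per CpG the age-gain difference was -5.20 points, with an exact permutation p of 0.0536.

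After 2 or 4 doses of 5-FU the age-gain score was 55.6% ± 1.5 (SD, n = 5), 0.643 points from the 0-dose group, with an exact permutation p of 0.607, and the age-loss score was 57.1% ± 1.77, a difference of -0.470 points with an exact permutation p of 0.714. With at least 3 reads per CpG the age-loss difference was -2.03 points, with an exact permutation p of 0.0357. Between donors, the age-gain score was 48.7% ± 3.39 (n = 6) for old and 45.2% ± 2.84 (n = 5) for young cells, with an exact permutation p of 0.108 and 0.309 adjusted. Among the 11 transplanted libraries, the one with the lowest age-gain score (41.5%) also read lowest at the CpG-rich tiles of intermediate level (43.1%). The one with the highest score (53.4%) read highest there (53.9%). Old and young libraries, which chose the tiles, differed there in the same direction. The score therefore cannot be read as a measure of age alone. Among tiles that gained with age, 2 lost with 2 doses of 5-FU where 0.62 would be expected of independent lists, and 0 gained with either dose.

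**Figure D3:**
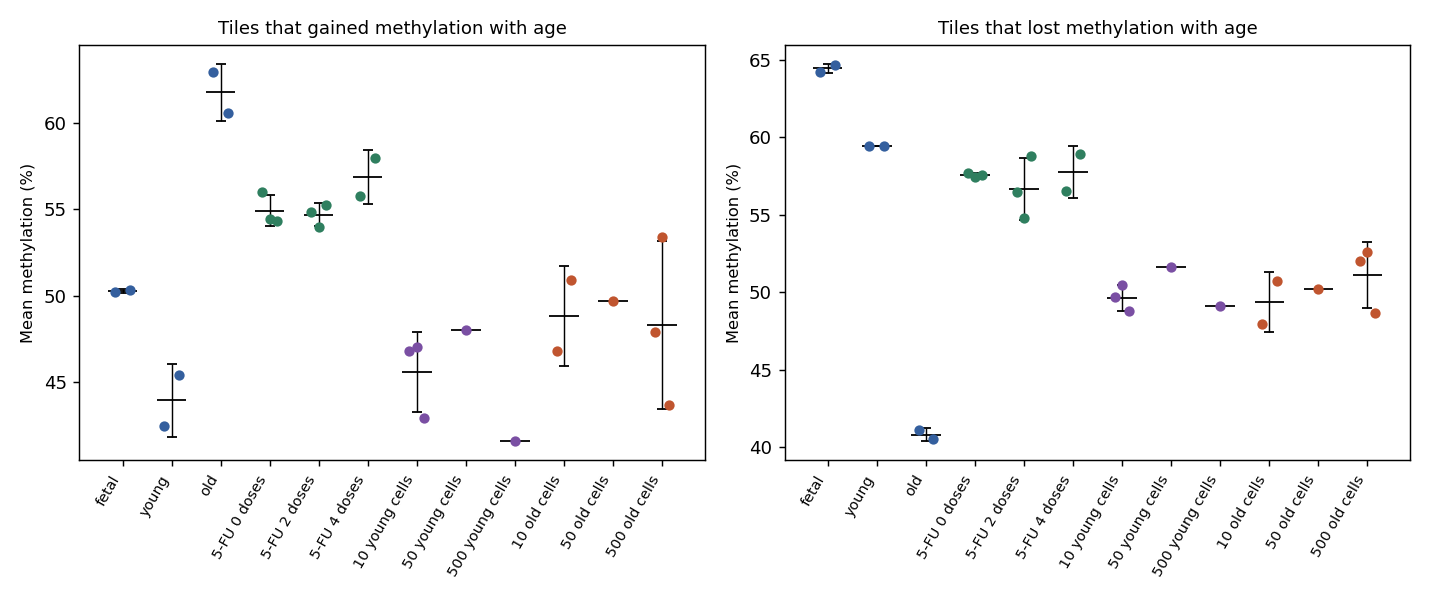
Mean methylation per library, in percent, over 2152 tiles that gained with age (left) and 174 tiles that lost with age (right). Points are libraries, long lines are group means and error bars are SD; young and old libraries chose the tiles, the 5-FU groups lie at 54.0% to 58.0% on the left, and the 5 young-donor libraries lie at 41.5% to 48.0%.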

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

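Chosen after the result was seen were the tests of the age pattern (that of conversion with tiles chosen again), the tests of cell number and of the X-linked mark against the loss, the test of autosomal unmethylated tiles, and the test of the difference between donor ages.

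After transplantation, X-linked tiles that are unmethylated in untransplanted HSCs were partly methylated, a signal on a chromosome the comparisons leave out. The median over 208 such tiles had a mean of 18.7% in the 11 transplanted libraries (8.25% to 24.6%), and was 0.0% to 1.37% in the 14 others. At 14244 autosomal tiles chosen in the same way the highest median of a transplanted library was 0.312%, which argues against incomplete conversion or a gain at all unmethylated tiles. A gain at a minority of the autosomal tiles would not show in a median. Cells with 2 X chromosomes may carry such a mark on the inactive copy, and the labels give no sex. The X over autosome depth at 1438 highly methylated tiles was 1.043 times that of the others (0.98 to 1.10 against 0.923 to 1.045); the bound set beforehand against this explanation, 5% above the others, was met by the mean but not beyond the spread, and depth at the 208 tiles, looked at afterwards, was 1.16 to 1.55 against 0.95 to 1.13, so the explanation stays open. The share of reads on chromosome Y was 0.0276% to 0.0463% in transplanted and 0.0462% to 0.0624% in other libraries.

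Loss at highly methylated tiles was found in all transplanted comparisons. Unequal recovery of methylated and unmethylated fragments stays open. With each library's offset removed, 27974 tiles lost and 688 gained with 10 young cells, a ratio of 40.66. At the 57 tiles that set the offset, 10 young cells read 49.2% and young 44.0%. The offset therefore ran against the loss there, and its removal could not have lowered the losses. With 10 and 500 old cells it ran with the loss, at 52.1% and 50.1% against 53.0% in old. Those 57 tiles are CpG-rich, while the loss was mostly at CpG-poor tiles. The number of cells transplanted goes with the loss, since libraries from 500 cells lay 3.912 points above those from 10 cells at highly methylated CpG-poor tiles (exact permutation p = 0.0079, the smallest possible, 0.0527 adjusted). The libraries from 50 old and 50 young cells read 85.5% and 87.4%. The highest libraries from 500 cells, 1 young and 1 old, read 90.04% and 89.2%. They also had the lowest X-linked mark of the 11, at 13.7% and 8.25%. The tile-wise comparison of 10 with 500 old cells called 0 of 90382 tiles. Over the 11 transplanted libraries the level at highly methylated CpG-poor tiles fell as the X-linked mark rose (r = -0.676, rho = -0.518), but without the 2 libraries farthest from the median mark r was -0.158. The mark also fell as the log2 depth of low (under 5% in every library) over high tiles (over 80% in every library) rose (r = -0.774, rho = -0.709). Without the same 2 libraries that r was -0.621. In the 11 libraries this depth went with the offset as well (r = -0.885, rho = -0.773). Transplanted and other libraries differ in the mark itself, so cells with 2 X chromosomes and the history of transplantation cannot be told apart as causes.

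The excess of gains in old over young HSCs went with a difference of the libraries at CpG-rich tiles of intermediate level. The log2 depth of low over high tiles, given above, was -0.270 in old and 0.160 in young libraries. Over the 14 untransplanted libraries the offset at the tiles of intermediate level fell as this depth rose (r = -0.632, rho = -0.380). Unequal recovery would give this direction. With this offset removed, gained tiles numbered 1.85 times the lost ones (1941 and 1049), and 50 resamples of the 57 tiles that set the offset gave 1.21 to 2.97. The bound of 1.5 lies within this range, so unequal recovery of methylated and unmethylated fragments stays open; the test was first read as excluding it, before its spread was computed. Incomplete conversion in the old libraries is argued against, since 14873 tiles chosen as low in the 10 fetal and 5-FU libraries alone read 1.54% and 1.84% in old and 1.23% and 1.053% in young libraries, a difference of 0.552 points. Ageing itself is also open, as the groups differ in age and in the offset alike.

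The effect of transplanting 10 cells differed between old and young donors at 183 of 90382 tiles, being higher in old donors at 40 and lower at 143, with 5785 tiles at an unadjusted p under 0.05. The p-value came from an interaction on the logit scale. The threshold of 10 points and the direction came from the difference of both effects in percentage points. These scales can disagree where old and young HSCs start at different levels. The difference of effects contains that between old and young HSCs.

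For 2 against 0 doses of 5-FU, 1 of the 10 splits of the 6 libraries, the real one with 25 tiles, gave as many changed tiles; the highest other gave 0, and 10 splits are too few for a share under 0.05. For donor age after transplantation, 9 of 100 drawn splits of the 11 libraries gave as many as the real 10 tiles, so chance cannot be excluded; the highest other gave 103, several times the real count, which points to a structure among the samples that was not identified or tested.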

How the results depend on the processing

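Removal of the offset, CpGs over 500 reads left out, centring, fits of only the groups compared and scores less matched tiles were chosen after seeing the data. The cause was not tested for any change below. With chromosome X included the totals of changed tiles stayed within 1.5 times the reported ones, but gained tiles numbered 1894, 1264 and 1058 with 10 young, 10 old and 500 old cells, in place of 1243, 640 and 516. With 10 reads per CpG, 2 and 4 doses of 5-FU against 0 gave 40 and 33 tiles, 10 and 500 old cells against old 16394 and 7535, and the age-gain difference after transplantation was -5.20 points; with 3 reads, 4 doses gave 14 tiles and the age-loss difference after 5-FU was -2.03 points. Tiles of 300 bp gave 388 for 0 doses against young, 117 and 73 for 2 and 4 doses, 2 for 10 against 500 old cells and 51 for donor age. With the offset removed, old against young gave 2990, 0 doses against young 152, 10 against 500 old cells 5 and donor age 22, and mean methylation differed by -0.692 (old minus young) and 0.544 points (young minus fetal); with reads pooled these were 10.0 and -3.23. Without CpGs over 500 reads, 4 doses gave 3 tiles, and chromosome 11, 103934001 to 103935000, reversed to 12.9 points; tiles left with fewer than 3 CpGs gave no value. A fit of all 25 libraries gave, in the order of the report, 1276, 180, 596, 216, 386, 2953, 4141 and 914, and 0 for donor age. At 20 points, young against fetal gave 3600, old against young 2726, and 10 young, 10 old and 500 old cells 4224, 7091 and 3182. Centred, 10 young and 10 old cells gave 11792 and 12566. With the replicate number as a block the counts were 3624 and 2380 for ontogeny and age, 92, 119 and 0 for 0, 2 and 4 doses, 2135 for 10 young and 4742 for 500 old cells, and 33 for donor age. Fits of only the groups compared gave 2883, 38 and 615 for 0, 2 and 4 doses, 40198 and 20141 for 10 and 500 old cells, and 56 for 10 against 500. With 0 doses as control 10 young cells gave 10227, and the tiles at chromosome 15, 49801001 to 49802000, and chromosome 4, 43043001 to 43044000, reversed to -13.5 and -4.10 points. limma gave 2843, 521, 760, 50, 60, 10380 for 10 young and 5539 for 500 old cells, and 0 for donor age, and the tile of chromosome 11 read 3.72 points. Less matched tiles, the age-loss difference after transplantation was -0.222 points.

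Leaving out each library in turn gave 4801 to 6567 tiles for young against fetal (lowest without fetal replicate 1), 2267 to 5830 for old against young (2267, 4003 and 2877 without old 1, old 2 and young 1), 29 to 177 for 0 doses against young (127, 119, 29 and 81 without 0-dose 1 and 3, young 1 and 2), 13 to 88 for 2 doses (15, 14 and 13 without 0-dose 1, 2 and 3, 88 without 2-dose 3), 4 to 930 for 4 doses (930 and 17 without 4-dose 1 and 2), 4765 to 20586 for 10 young cells (lowest without young 2), 10834 to 18825 for 10 old cells (12613, 10834 and 13856 without 10-cell 1, old 1 and old 2), 2618 to 12355 for 500 old cells (2618, 4340 and 6415 without old 1, old 2 and 500-cell 1), 0 to 2 for 10 against 500 old cells (2 without 500-cell 2) and 0 to 78 for donor age (the libraries are named in the report). Where a group kept 1 library, it was assumed to vary like the others. Mean methylation moved between 1.65 and 2.33 (old minus young) and between -0.568 and 0.111 points (young minus fetal), the age-gain difference between -10.4 and -8.76 (transplanted) and 0.037 and 1.17 (5-FU), and the age-loss difference between -8.07 and -7.35 and between -0.934 and 0.115. Of the values of 51 named tiles, counted 62 times because some are named in several comparisons, under other settings 282 kept direction and side of the threshold, 33 no longer passed it and 4 reversed. With a library left out 277 kept both and 25 no longer passed. These counts leave out tiles that were not tested in a setting. With 10 reads per CpG 35 kept both and 1 no longer passed, and in a fit of all 25 libraries 28 and 5. The tiles were chosen for the largest differences in the same libraries, which favours their being kept. The test of gene lists and its alternative on promoter tiles were not run. Depth limits how many tiles can be tested: 57204 for 5-FU and 100896 for ontogeny and age.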

Other observations

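The check of unequal depth and the classing of tiles by a group outside the comparison were chosen after the result was seen, and so were the tiles of the test of domains, whose first form was fixed before.

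Loss after transplantation was uneven along chromosomes. Over 1052 bins of 1 Mb with at least 20 of 47992 tiles at 80% or more in fetal HSCs, which are outside both comparisons, the bin means with 10 young cells had an SD of 1.768 points, against 1.34 to 1.51 in 100 shuffles of tiles among bins within classes of CpG number. Bin means of 10 young cells against young and of 10 old cells against old, which share no library, correlated with r = 0.762, and single tiles with r = 0.572. With tiles chosen by their mean over the libraries of the fit, which leaves out tiles that lost most, the SD was 1.39 points, against 1.11 to 1.29, and r was 0.642. An organisation of the loss in domains of a megabase may explain this, as a hypothesis. By the mean of both comparisons, the strongest loss was at chromosome 7, 137000001 to 138000000 (-12.1 points with young and -16.9 with old cells), followed by chromosome 11, 80000001 to 81000000 (-12.6 and -16.1), and the weakest at chromosome 6, 107000001 to 108000000 (-2.95 and -6.03).

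Runs of gained tiles exceeded the random draws after transplantation too: with 10 young cells 7 runs held 3 or more gained tiles, against at most 1 in 100 random draws. Runs of lost tiles, 48, 104 and 26 with 10 young, 10 old and 500 old cells, did not exceed the highest of the random draws, 84, 177 and 33. With 10 young and 10 old cells they lay below the mean of the draws, 66.5 and 148. The draws were not matched on level or CpG number. Clustering of the change thus cannot be told apart from that of tiles of such classes. With 500 old cells a run at chromosome 8, 125198001 to 125202000, had a median gain of 22.8 points. Its first tile read 65.3% ± 3.19 (SD, n = 2) in fetal HSCs and 48.3% ± 17.0 (n = 3) with 0 doses of 5-FU.

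Tiles whose depth differed more than 10-fold between groups, relative to library depth, were 20 of 8061 changed tiles for young against fetal, 31 of 6236 for old against young, 18 of 237 for 0 doses against young, 3 of 25 for 2 doses and 3 of 6 for 4 doses. The replicate numbers of the labels were not treated as pairs: deviations from the group mean of libraries with the same number correlated between -0.0761 and 0.147 across groups.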
